A study of Mus musculus with 32 samples.

How the data were processed

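Gene expression was measured with Affymetrix HT MG-430 PM arrays in macrophages grown for 9 days from the bone marrow of chimeric female mice. According to the labels, recipients were C57BL/6J mice of 8 weeks that received 2 gamma exposures of 550 rad each and were then given marrow from congenic B6.SJL-Ptprca donors. The donors had been exposed to UV radiation at 8 kJ/m2 on the shaved back 3 days before the marrow was taken (UV chimeric), or had only been shaved (control chimeric). At least 500 ng of RNA was sent for each array. There were 32 arrays in 4 groups of 8, control or UV chimeric and untreated or LPS. The labels do not say whether mice or cultured cells were exposed to LPS, nor its dose and duration. They do not say whether the 8 arrays of a group came from separate animals, so the p-values measure the spread between these arrays, which may be partly technical.

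The deposited values are log2 expression values, and the submitters' processing notes name affy, RMA and limma without versions. RMA subtracts background, sets the distributions of the arrays equal and summarises the probes of a set. The sources used here do not state whether all arrays went through it together. The identifiers are Entrez gene numbers, 1 row per gene, and the chip definition behind them is not given in the sources used here. Scanner files were not used here, so background correction and summarisation were not repeated. The table had 17856 rows and 0 missing values. The platform table gave 1 gene symbol for 17216 rows, several for 0 and none for 640. In each of the 17216 named rows the number in the identifier was the Entrez number of the named gene, and the RefSeq table for GRCm38.p6 gave the same symbol. The identifiers therefore pair with the symbols, but the values beside them fail several simple checks of gene identity, which the report gives first. For this reason genes appear below as row labels ("the row labelled Rtn1"), and no value is taken here as evidence about the gene of that name.

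All 32 arrays were fitted together in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with 1 mean per group, moderated variances and Benjamini-Hochberg adjustment over the 17856 rows. The threshold was an adjusted p of 0.05, and counts with an absolute log2 change of at least 1 were also made. The contrasts were UV against control chimeric in untreated and in LPS arrays, their mean, LPS against untreated in each chimera type, and the UV by LPS interaction. The row labelled Rtn1 also had a two-sided permutation test over all 12870 regroupings of the 16 arrays of a treatment. Before the data were examined, 33 gene lists were fixed, and 697 of their 784 symbols were matched to rows through current or older symbols. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The lists reported by name are reticulons, chemoattractant receptors, adhesion and cell migration, macrophage identity, inflammatory cytokines, chemokines, interferon-stimulated genes, cell cycle and cholesterol synthesis. Named rows followed a rule fixed at the same time. It took Rtn1, then the 10 largest changes in each direction past the threshold or, where fewer than 5 rows passed, the 5 smallest p in each direction, and then list members. Further rows were named after their values had been seen, to check the labels. Intervals of differences between family medians come from 10000 bootstrap draws of rows.

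On simulated data with the spread of these arrays, 95% of 100 rows given a log2 change of 1 were recovered in each UV comparison. Of 100 rows given a change of 0.5, 67% were recovered in the untreated and 60% in the LPS comparison. Among rows given no change, 8 were called in the untreated and 11 in the LPS comparison. The simulated noise was independent between rows and arrays, without the joint deviations of same-numbered arrays given below. These rates may therefore differ from the sensitivity on the real arrays. The number of arrays limits the precision, and the median 95% half-width of a difference between groups of 8 was 0.24 log2 units.

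The groups share replicate numbers 1 to 8. Deviations from the group means correlated between same-numbered control and UV arrays under LPS in every pair (r = 0.35 to 0.61 across rows). They also did so between same-numbered untreated and LPS arrays of the UV chimeric type (r = 0.10 to 0.23). Every same-numbered pair passed a limit of 0.1 there, on the evidence of the values alone, since the labels name no shared litter, batch or day. Between control and UV arrays under LPS the mean correlation was 0.43 for the same number and -0.06 for other numbers. There 10 of 16 arrays correlated best with their own number, while the rest correlated better with another number. Control and UV untreated arrays had 14 of 16, though 1 pair lay at 0.05. Alternatives were the number as a block, another normalization, filters on dim rows, other variance models, array weights, fewer groups, other thresholds and leaving out each array. The table has 1 row per gene, so alternatives over several probe sets of a gene reduced to the 17216 named rows.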

Results

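Expression was measured on 32 arrays of mouse bone marrow-derived macrophages, 8 in each of 4 groups (control or UV chimeric, untreated or LPS). The title of the series names reticulon-1 and reduced migration toward chemoattractants, so the comparisons ask how a UV exposure of the marrow donors altered macrophage expression, with and without LPS, a bacterial cell wall component. Array medians ranged from 3.58 to 3.66 log2 units in the 16 untreated arrays and from 2.96 to 3.07 in the 16 LPS arrays.

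Several rows had levels that would be unusual for the named genes in macrophages, though levels of different rows also depend on the affinity of their probes. The row labelled Xist, the transcript of the inactive X chromosome in female cells, had 1.64 ± 0.31 (SD, n = 16) in untreated arrays, at the 17.9th percentile of rows, while the row labelled Uty, a Y-linked gene that female mice lack, had 7.46 ± 0.08. Other Y-linked rows were low, with 1.32 ± 0.20 for Kdm5d and 1.87 ± 0.22 for Eif2s3y, and the 7 rows of the Y-linked list had a median of 1.87. The sex stated above is that of the chimeric mice, and the reading of Xist and Uty assumes that the marrow donors were female too. The contrast between Uty and the other Y-linked rows does not rest on that assumption. The row labelled Alb, the albumin gene of the liver, lay at 7.44 ± 0.12. Several rows labelled with abundant macrophage genes lay far lower. Csf1r, the receptor for macrophage colony-stimulating factor, had 2.06 ± 0.33, Cd68 had 2.04 ± 0.28, and Ctsd, a lysosomal protease, had 1.84 ± 0.16. B2m, the light chain of class I molecules, had 1.73 ± 0.13, and the iron storage gene Fth1 had 2.17 ± 0.18 (SD, n = 16 each). The macrophage identity list had a median of 3.14 over 28 rows, against 3.62 over all rows. Over all arrays its median of 2.90 lay at the 34.7th percentile of random lists of the same size, so the list as a whole did not stand out.

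Families of genes that nearly every cell uses had, pooled over 129 rows and all arrays, a median of 2.96, and families restricted to other tissues one of 3.42 over 169 rows (difference -0.46, bootstrap 95% interval -1.72 to 1.27). Levels of different rows also depend on the affinity of their probes. In untreated arrays the median level was 2.05 over 25 rows labelled as ribosomal protein genes, 2.73 over 40 proteasome rows and 3.97 over 64 respiratory chain rows. Among the restricted families it was 3.52 over 37 olfactory receptor rows, 2.65 over 26 vomeronasal receptor rows, 2.92 over 86 keratin rows and 3.95 over 20 defensin rows. The highest rows were labelled Cntrob (12.66), Pi15 (12.51), Ccn2 (12.51) and Muc2 (12.17). Some rows labelled with genes active in macrophages lay above the median row, such as Actb at 8.36 ± 0.15 and Tyrobp at 6.98 ± 0.16. Adgre1, the F4/80 antigen, lay at 6.29 ± 0.09 and Ctsb at 5.90 ± 0.12 (SD, n = 16). Apart from Actb these rows lay below those labelled Alb and Uty, so their levels do not show that their labels are right. All gene names below are therefore labels of rows as the table gives them.

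**Figure D1:**
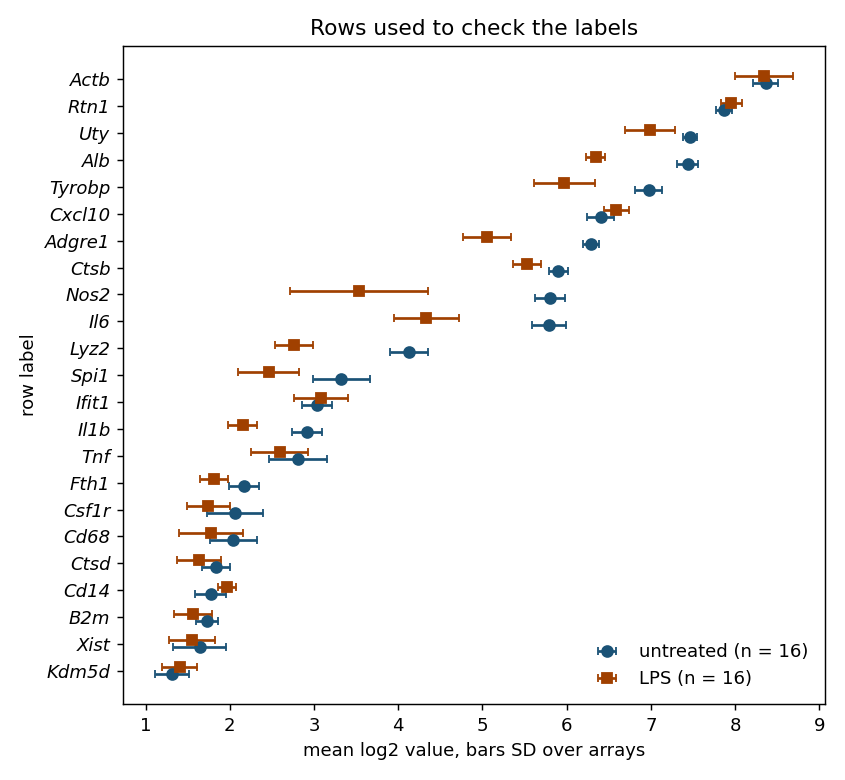
Mean log2 value (x axis) of rows named by their labels (y axis), with SD over 16 untreated (circles) and 16 LPS arrays (squares). The row labelled Uty (7.46 untreated) lies far above those labelled Xist (1.64), Csf1r (2.06) and Cd68 (2.04).

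The row labelled Rtn1 did not differ detectably between UV and control chimeric arrays. In untreated arrays it had 7.86 ± 0.10 (SD, n = 8) in the control and 7.88 ± 0.11 in the UV group. The difference was 0.02 log2 units, with a 95% interval from -0.12 to 0.16 (two-sided permutation test over 12870 regroupings, p = 0.705). In LPS arrays it had 7.94 ± 0.12 in the control and 7.97 ± 0.14 in the UV group, a difference of 0.04 with an interval from -0.10 to 0.17 (permutation p = 0.597, and 0.705 for both after adjustment over the 2 comparisons). LPS against untreated gave 0.08 ± 0.07 (SE) in control chimeric arrays (limma, adjusted p = 0.321). This value depended on the scaling, with 0.29 ± 0.07 after quantile normalization (adjusted p = 0.000403) and 0.70 ± 0.07 after median centring (adjusted p = 1.14e-10).

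**Figure D2:**
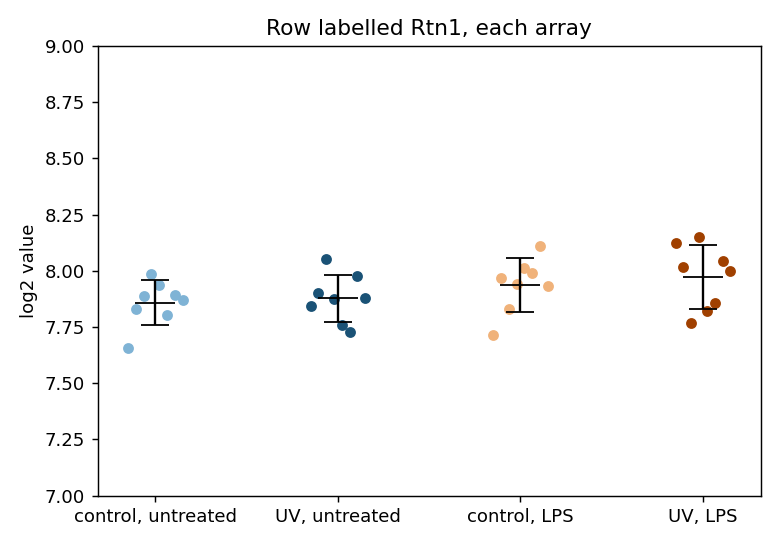
Log2 value of the row labelled Rtn1 on each array (points), with mean and SD per group of 8. Group means run from 7.86 to 7.97 and the groups overlap.

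No row differed between UV and control chimeric arrays in untreated cells. The smallest adjusted p in limma was 0.883, for the row labelled Ubr4, which was -0.38 ± 0.08 (SE). An unadjusted p under 0.05 was reached by 497 of 17856 rows, where 893 would be expected by chance. That count depends on the fit. With the replicate number as a block within untreated arrays it was 1072, and other blocked fits gave fewer, as given under other observations. In the fit without a block, the next smallest p after Ubr4 belonged to rows labelled Ccdc73 (-0.47 ± 0.12), Pik3r4 (-0.54 ± 0.14) and Zfp90 (0.59 ± 0.16), none past the threshold. The row labelled Irak2, an inner component of Toll-like receptor signalling, differed by 0.45 ± 0.13, and that labelled Ltb4r1, the leukotriene B4 receptor, by -0.48 ± 0.14 (SE, adjusted p above 0.99 in limma for both). The interval of the difference lay within 1 log2 unit of 0 in 17771 rows (99.5%) and within 0.5 in 15503 rows (86.8%). These counts do not use the names, but it was not tested whether each row holds the probes of 1 transcript. In control untreated arrays 40% of rows lay at or below 2.39, where signal over background cannot be judged. A narrow interval in such rows does not exclude a change of the transcript. The rows labelled Ubr4, Pik3r4 and Zfp90 had group means between 1.19 and 2.20 in these arrays.

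In LPS arrays 0 rows passed as well, with 746 at an unadjusted p under 0.05, where 893 would be expected by chance. That count depends on the fit. With the replicate number as a block within LPS arrays it was 1283, and other blocked fits gave fewer, as given under other observations. The row labelled Adck2 had the smallest adjusted p (0.197 in limma) and was 0.78 ± 0.15 (SE) higher in the UV group. Without UV LPS replicate 2 it passed, with 0.87 and an adjusted p of 0.0269. The row labelled Faap24 was -0.65 ± 0.15 (adjusted p = 0.835), and it alone passed after quantile normalization (-0.83, adjusted p = 0.0271). By p, rows labelled Elovl4 (0.68 ± 0.16), Gm4951 (0.45 ± 0.11), Zfp385a (0.55 ± 0.14) and Fbh1 (0.60 ± 0.15) came next. The interval lay within 1 log2 unit of 0 in 17745 rows (99.4%), with the same limit for dim rows.

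The interaction of UV and LPS also gave 0 rows in limma, with 579 at an unadjusted p under 0.05. The row labelled Ccdc73 had the smallest p (0.74 ± 0.17 SE, adjusted p above 0.99), followed by 9430038I01Rik (0.81 ± 0.20), Apex2 (0.56 ± 0.14) and Ripor3 (0.63 ± 0.16). Averaged over both treatments, 0 rows passed and 604 had an unadjusted p under 0.05. The smallest p there belonged to Ubr4 (-0.26 ± 0.06) and Nuak1 (0.33 ± 0.08), both with an adjusted p of 0.948.

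No fixed list passed camera in any of these UV contrasts. The lists are sets of row labels, which failed the checks above, so these tests do not decide whether the named pathways changed. The macrophage identity list came nearest in untreated arrays, with a median difference of -0.04 over 28 rows (adjusted p = 0.146, and adjusted p = 0.110 with an estimated correlation). Among 19 chemoattractant receptor rows 0 were called over all rows and 1 when adjusted over the list alone, that labelled Ltb4r1 having the smallest p, and the list had an adjusted p of 0.676. The adhesion and cell migration list (37 rows, 0 called) had an adjusted p of 0.676 in untreated and 0.883 in LPS arrays. The 7 reticulon rows had 0 calls and adjusted p of 0.867 and 0.883.

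LPS arrays differed from untreated ones in most rows. In control chimeric arrays 10600 of 17856 rows were called, 2528 higher and 8072 lower, and 3692 of them changed by at least 1 log2 unit. The row labelled Luc7l3 rose from 1.42 to 10.37, and that labelled Slc35b4 from 4.84 to 12.47. Rows labelled Cadm3 (7.46 ± 0.14 SE) and Rac2, a GTPase of blood cells (7.21 ± 0.13), also rose. Rows labelled Tmem150a (-6.60 ± 0.17), Khk, a fructose kinase (-6.53 ± 0.19), Them7 (-6.44 ± 0.13) and Vipr1 (-6.13 ± 0.19) fell. The adjusted p in limma was 4.2e-19 or smaller for each of these. The lower mean of these rows, Slc35b4 aside, lay between 1.27 and 2.44, below the array medians, where signal over background cannot be judged, so the sizes are differences of deposited values and may understate the change.

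The split between higher and lower rows was set by the scaling. The median row changed by -0.21 log2 units in control chimeric arrays, and the mean array median of the LPS set lay -0.62 from that of the untreated set. Quantile normalization gave 4741 higher and 5051 lower rows, and median centring 10897 higher and 3394 lower. The large changes kept their direction under both, with 8.94 and 9.57 for Luc7l3 and -6.46 and -5.98 for Tmem150a.

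**Figure D3:**
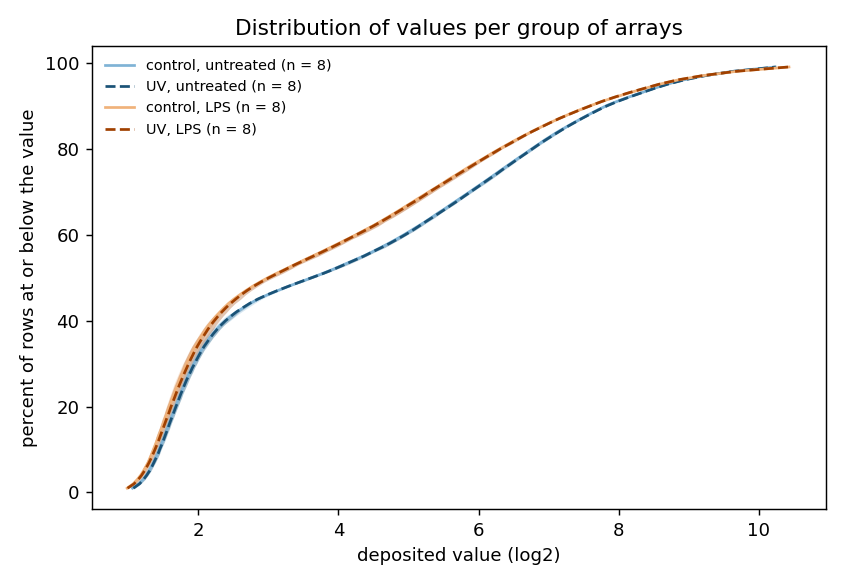
Percent of rows (y axis) at or below a log2 value (x axis) for each group of 8 arrays; lines are group means and bands the range over arrays. The UV and control curves coincide, while LPS and untreated curves part, with array medians near 3.00 and 3.62.

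In UV chimeric arrays the difference between LPS and untreated arrays was nearly the same. There 10483 rows were called, 2539 higher and 7944 lower (4737 and 4948 after quantile normalization, 10859 and 3410 after median centring). Of the calls 9366 were shared, each with the same sign, and the changes in both chimera types correlated at r = 0.985 across rows, which are not independent replicates. Treatment and array set coincide, so a difference between the sets common to both chimera types would give such a likeness too. The row labelled Luc7l3 rose by 8.55 ± 0.41 (SE), Cadm3 by 7.43 ± 0.14 and Rac2 by 7.12 ± 0.13, and Khk changed by -6.89 ± 0.19. The interaction contrast above is the test of a difference between the chimera types.

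Several rows labelled with well-known LPS-response genes did not rise in the deposited values. In control chimeric arrays the change was -0.15 ± 0.17 (SE) for Tnf, -0.76 ± 0.09 for Il1b, -1.49 ± 0.15 for Il6 and -2.50 ± 0.28 for Nos2, the inducible nitric oxide synthase. It was 0.03 ± 0.13 for the interferon-induced Ifit1 and 0.13 ± 0.08 for the chemokine Cxcl10. After quantile normalization Ifit1 and Cxcl10 were higher in LPS arrays (0.55 ± 0.14 and 0.59 ± 0.08), and after median centring so was Tnf (0.47 ± 0.17, SE), while Il6 and Nos2 remained lower under both. Of 22 inflammatory cytokine rows 1 rose and 9 fell (10 called when adjusted over the list alone). Of 34 interferon-stimulated rows 3 rose and 19 fell (22 over the list alone), and of 22 chemokine rows 3 rose and 8 fell (11 over the list alone). These splits follow the scaling too: quantile normalization gave 3 higher and 9 lower, 6 and 8, and 6 and 4 rows for the 3 lists in that order, and median centring 11 and 5, 16 and 7, and 13 and 2. No list of the 33 passed camera in either chimera type, the smallest adjusted p being 0.793 and 0.767. With fry, which does not set a list against other rows, 32 and 30 lists passed.

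Arrays of the same replicate number deviated together. The first principal component of the untreated arrays held 20.7% of their variance and parted numbers 6, 7 and 8 from numbers 1 to 5. That of the LPS arrays held 28.5% and set numbers 6 and 8 apart. UV and control arrays were balanced over these sets. Within numbers 1 to 5, 0 rows passed for UV against control in untreated or LPS arrays (592 and 728 at an unadjusted p under 0.05), and within numbers 6 to 8 again 0 (409 and 783).

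**Figure D4:**
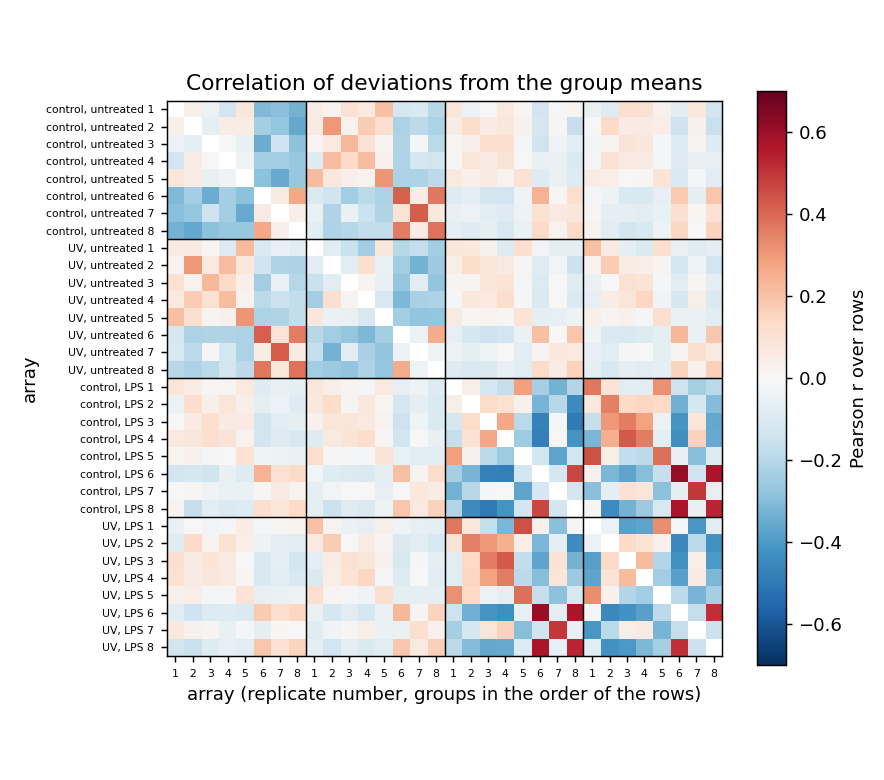
Pearson correlation over rows (colour) between arrays after subtracting group means, in 4 groups of 8; both axes list arrays by group and replicate number. Same-numbered control and UV arrays under LPS correlate between 0.35 and 0.61.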

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

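The split tests of the UV comparisons, the tests of levels and orders of the labels, of the distribution gap and of the replicate numbers were chosen after the values had been seen; the coherence test of the gene lists and the split tests of the LPS comparisons were not.

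Values standing apart from the other 7 arrays of their group were found in 23 of 360 sets of 8 values, where chance gives about 18. Among control untreated arrays these were replicate 2 in the rows labelled Irak2 (1.74, others 2.10 to 2.30) and Cyp51 (1.74, others 1.18 to 1.41), and replicate 8 in Xist (2.50). Among UV untreated arrays they were replicate 1 in Zfp90 (2.66), replicate 3 in Ubr4 (1.41), replicate 6 in Luc7l3 (2.35), replicate 4 in Serpinf2 (1.55) and 4930449C09Rik (3.05), and replicate 8 in D10Wsu102e (4.88). Among control LPS arrays they were replicate 6 in Il20 (7.03) and Tmem150a (1.62), replicate 3 in Vac14 (0.91), replicate 8 in Cyb5r3 (1.88), replicate 4 in Cd68 (2.19) and replicate 5 in Rpl13a (2.29). Among UV LPS arrays they were replicate 1 in Ubr4 (1.07) and Eif2s3y (2.91), replicate 3 in Ltb4r1 (2.37), replicate 2 in Abcb8 (1.11), replicate 4 in Dhx58 (2.24), replicate 7 in Ddr2 (2.95), replicate 6 in Rnf145 (1.96) and replicate 5 in Saa3 (1.87).

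The first pattern is the mismatch between row labels and values. If the labels belonged to the values and arrays of a group differed biologically, rows of one pathway should vary together between arrays. Only 1 of 33 lists lay above the 95th percentile of 10000 random lists. The percentiles of cell cycle, interferon-stimulated genes and cholesterol synthesis were 85.5, 40.1 and 67.6. A largely technical spread between arrays could also leave lists without joint variation. Rows labelled as everyday genes lay -0.46 log2 units from rows of tissue-restricted genes (bootstrap 95% interval -1.72 to 1.27). Random labels gave -1.38 to 1.41. Levels of different rows also depend on probe affinity, a spread that the interval over rows includes. Everyday genes should lie well above restricted ones in any kind of cell, so for these families the values argue against cells of another kind. With the labels sorted by number, by symbol or in reverse the difference was 0.44 at most (interval -1.26 to 1.46), which argues against these orders in the same way. Candidate explanations left open are labels parted from values in some other way and, untested, a chip definition that grouped probes of different genes.

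The second pattern is the gap between the distributions of LPS and untreated arrays. The mean array medians differed by -0.62 log2 units, while the median SD of sorted values at a rank was 0.02 within the untreated and 0.03 within the LPS set. RMA sets the distributions of arrays run together equal before it summarises probes. A gap this far beyond the spread within a set argues against a joint run, though summarisation can still move values. After separate runs a broad effect of LPS could remain as a gap, and so could a technical difference between the sets. Treatment and array set coincide, so these cannot be told apart.

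The third pattern is the joint deviation of same-numbered arrays. Of 32 arrays 24 had their closest partner of the other chimera type and same treatment in their own number; random numberings gave a median of 4 and at most 20 (permutation p = 1e-05, the smallest that 100000 numberings can give). A batch shared by each number, such as a day of culture or hybridisation, may be the source, and shared litters or cages remain untested.

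Other splits of the same arrays were compared with the real ones, 100 in each case with the real one included. In each UV contrast the real split gave 0 rows, which all 100 splits must reach, so the count past the threshold tests nothing there. The highest of the other splits gave 242 rows in untreated arrays, 3243 in LPS arrays, 9 for the interaction and 1 for the mean of both treatments. The splits with many calls point to a structure of the arrays that the groups do not follow. At an unadjusted p under 0.05, at least as many rows as in the real split were found in 64 of 100 splits for untreated arrays, 78 for LPS arrays, 81 for the interaction and 78 for the mean, so chance is not excluded by that count. These splits ignore the replicate numbers, although same-numbered control and UV arrays deviated together under LPS. With swaps within numbers in a blocked fit of the LPS arrays, 4 of 100 reached the real count. For LPS against untreated, 1 split of 100, the real one, reached 10600 rows in control chimeric arrays (highest other 8964). In UV chimeric arrays 1 reached 10483 (highest other 4529). The real counts thus lay above those of every other split drawn. The splits cannot tell LPS from a difference between the array sets, since treatment and array set coincide.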

How the results depend on the processing

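The number of rows called for LPS against untreated stayed within 1.5 times its value under every alternative run, but the rows behind it changed more. After quantile normalization 7515 of the 10600 rows in control chimeric arrays were called again with the same sign, and 342 with the opposite sign. In UV chimeric arrays 7442 of 10483 kept their sign and 362 reversed. The counts of 0 for UV against control in untreated arrays, for the interaction and for the mean of both treatments stayed at 0. For UV against control in LPS arrays, quantile normalization gave 1 row and leaving out each array in turn 0 to 1 rows (1 without UV LPS replicate 2 and 1 without replicate 3, the row labelled Adck2 both times). The row labelled Rtn1 had differences from -0.0089 to 0.041 in untreated arrays and from 0.0032 to 0.065 in LPS arrays when each array was left out, turning sign without control untreated replicate 1 (-0.0089) and without UV untreated replicate 3 (-0.0052). Within replicate numbers 6 to 8, an alternative chosen after seeing the data, it was -0.044 under LPS. None of these Rtn1 values passed the threshold, and the cause was not tested. With the replicate number as a block, LPS against untreated gave 10947 rows in control and 10806 in UV chimeric arrays, UV against control again 0 in each contrast, and no other call changed. Same-numbered control and UV untreated arrays correlated from 0.05 to 0.43, so 1 pair missed the limit of 0.1, and 14 of these 16 arrays correlated best with their own number, against 10 of 16 for control and UV arrays under LPS. Same-numbered untreated and LPS arrays of the control chimeric type correlated from 0.06 to 0.24, with 13 of 16 arrays closest to their own number. The list tests of LPS against untreated went from 0 lists with camera to 32 (control chimeric) and 30 (UV chimeric) with fry, by the construction of fry. Averaging several probe sets of a gene was not run, since each gene has 1 row. Signal over background cannot be judged without scanner files.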

Other observations

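Counts of rows at an unadjusted p under 0.05 were followed further, because same-numbered arrays deviated together. With the number as a block within LPS arrays, a fit chosen after seeing the data, 1283 rows of 17856 reached such a p for UV against control. That excess over the 893 expected by chance had been seen before the test, and it depends on the fit: with all arrays, the number as a block gave 1035 rows, and the random block within chimera type 739. Among 100 swaps of chimera type within replicate numbers, the real one included, 4 gave as many rows (median 857.5, highest other 1588). In untreated arrays the count was 1072, which 8 of 100 swaps reached, against 619 and 491 in the same 2 fits of all arrays. Whether there were many small UV differences under LPS, each below the threshold, is left undecided by these values, since the fit and the count were chosen after the excess was seen.

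A small UV effect shared by both treatments was tested through the UV differences in untreated and in LPS arrays. They correlated at r = 0.02 across rows, and 51.5% of rows had the same sign. Of 128 joint swaps of chimera type within numbers 101 gave a correlation at least as high (median 0.06), so the values argue against a shared effect large enough to stand out from this structure.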
